A study of Mus musculus with 12 samples.

How the data were processed

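Gene expression was measured by RNA sequencing in 12 libraries of whole mouse kidney. Per the labels' protocols, kidneys were ground under liquid nitrogen, lysed in Trizol and cleaned on a Direct-zol column, and double-stranded cDNA was made with a SMARTer Ultra Low kit. The submitters' processing notes name bcl2fastq, STAR 2.5.1a, Subread, featureCounts 1.4.6-p5, Salmon 0.8.2 and the mm9 build, without saying which tool made which table. The deposited gene table holds estimated counts per Ensembl gene, and the deposited values of 21.6% of genes are not whole numbers. A deposited table of moderated log2 CPM was used only as an alternative input, and its prior count is not given in the sources used here. Other deposited tables, per transcript or scaled, were not analysed here. Whether counting used strand is not given in the sources used here, so a gene and an antisense partner cannot be told apart.

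The gene table has 55774 lines for 55487 gene IDs, and 287 repeated lines were dropped. Estimated counts were rounded to whole numbers. Symbols were taken by gene ID from a reference table of names, and no coordinates are given because the build in the notes is not that of the reference at hand. Groups were read from the sample titles and genotype labels, with homo titles as KO and het titles as controls. Choices of tests, lists and the rule for named genes were made before the data were examined.

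Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr, which left 19890, and libraries were scaled by TMM. One quasi-likelihood fit of all 12 libraries with 4 groups (common biological coefficient of variation 0.238) gave every comparison, and adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. Standard errors were derived from the fold change and its test. CPM values are scaled by TMM and are given as mean and SD of 3 libraries. Library totals of 23070736 to 31837973 counts limit precision for weak genes, and these limits cover counting error only.

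Named genes were, for each of the Cep120 and Pkd1 comparisons, the 8 largest rises and 8 largest falls among genes past the threshold with a mean log2 CPM of at least 1 and no overlap between groups, and 4 and 4 for the difference and the controls. Clone-named, mitochondrial, immunoglobulin and sex-linked genes were left out. To these were added the targeted genes and up to 4 members of each list with the smallest p. Where a text names another member of a list, another gene of a small count or a gene family, it was chosen after its values were seen.

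There were 32 gene lists, written from textbook knowledge for matrix, myofibroblast and stromal cell, tubular injury, macrophage, T and B cell, neutrophil, chemokine, Wnt, Hedgehog, Notch, TGF-beta and BMP, YAP and TAZ, cell cycle, p53, centrosome and cilium, principal cell, intercalated cell, ureteric bud tip, nephron progenitor, proximal tubule, loop of Henle, distal convoluted tubule, podocyte, endothelial cell, fatty acid oxidation, renin and angiotensin, red blood cell, adrenal, adipose, skeletal muscle, urothelium and immediate early genes. They were tested with camera at a preset correlation of 0.01 on log2 CPM with a prior count of 2, adjusted over the 32 lists of a comparison. Camera with an estimated correlation and fry were run beside it. List scores per library are the mean over members of log2 CPM minus its mean in the 6 control libraries.

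The fit was tested on simulated counts drawn from the means, spread and library sizes of these libraries, in 10 simulations of 19890 genes. In each, 200 genes were changed for each comparison, and the matrix list was also raised 1.5-fold in Cep120 KO. Genes were drawn independently, so shifts that many genes share, as with sex or the detected-gene classes, are not in them. For the Cep120 comparison 54.6% of 2-fold and 89.4% of 4-fold changes were recovered with 3.94% false calls, and for the Pkd1 comparison 51.5% and 90.3% with 2.84%. In the Cep120 comparison 8.51% of 1.5-fold changes were recovered.

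Alternatives were RLE and upper quartile scaling, DESeq2 1.42.0, voom, no filter, a filter of 5 CPM in 3 libraries, the libraries of 1 comparison alone, the replicate number as a block, the deposited log2 CPM, pooled controls, other thresholds, and each library left out in turn. Terms for sex and for the number of genes detected (split at 28000), and the fit without both replicate 3 controls, were chosen after seeing the data. Sex was coded in 3 ways, as Y-linked RNA relative to the 5 Xist-free libraries, as the same relative to the Pkd1 KO libraries, and as Xist absent or present, each with and without the detected-gene term. Xist absent or present varied within a group only in Cep120 KO. Under that coding the sex effect comes from Cep120 KO 1 and 2 against Cep120 KO 3, and is not an adjustment within the Pkd1 line.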

Results

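RNA from whole kidneys of mice at postnatal day 15 was sequenced in 12 libraries, 3 for each of 4 groups. Cep120 is a centriole protein and Pkd1 encodes polycystin-1, and Hoxb7-Cre acts in the ureteric bud and in the collecting duct that grows from it. Each line had 3 libraries labelled KO and 3 whose titles say het and whose genotype label says WT, called Cep120 controls and Pkd1 controls here. The labels do not say that the 3 libraries of a group came from separate animals, so the p-values measure the spread between libraries. Cep120 controls 1 and 2 stood far closer to each other than any other pair within a group. Their chi-squared per gene, a difference measured against sampling noise, was 5.80, and that of the other pairs 28.3 to 76.5. Total counts were 25562919, 28065446 and 26949415 in Cep120 KO 1 to 3, and 24290908, 25111721 and 26838172 in Cep120 controls 1 to 3. They were 28301257, 31216756 and 26838888 in Pkd1 KO 1 to 3, and 31837973, 23070736 and 24667239 in Pkd1 controls 1 to 3.

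The targeted genes come first, since they check the labels. Cep120 (ENSMUSG00000048799) was at 17.9 ± 2.16 CPM (SD, n = 3) in the libraries labelled Cep120 KO and 16.2 ± 2.51 in their controls, with a log2 fold change of 0.14 (SE 0.16). It was at 26.4 ± 2.64 CPM in the libraries labelled Pkd1 KO and 17.8 ± 3.17 in the Pkd1 controls. Pkd1 (ENSMUSG00000032855) was at 28.8 ± 6.69 CPM in the libraries labelled Pkd1 KO, where it rose against 17.2 ± 3.998 in their controls by 0.74 on the log2 scale (SE 0.20, edgeR adjusted p = 0.00952). That call ended without Pkd1 KO 1 and with each of 6 sex terms, with a log2 fold change down to 0.36 and an adjusted p up to 0.378. It was at 23.2 ± 2.74 CPM in the libraries labelled Cep120 KO and 19.9 ± 3.72 in theirs. Neither gene was lower in the libraries labelled as its knockout, so whole-kidney RNA does not check these labels, and every direction below rests on the labels alone. Which part of either gene was deleted is not given in the sources used here, and RNA from outside that part, or from cells in which Hoxb7-Cre is not active, would still be counted.

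**Figure D1:**
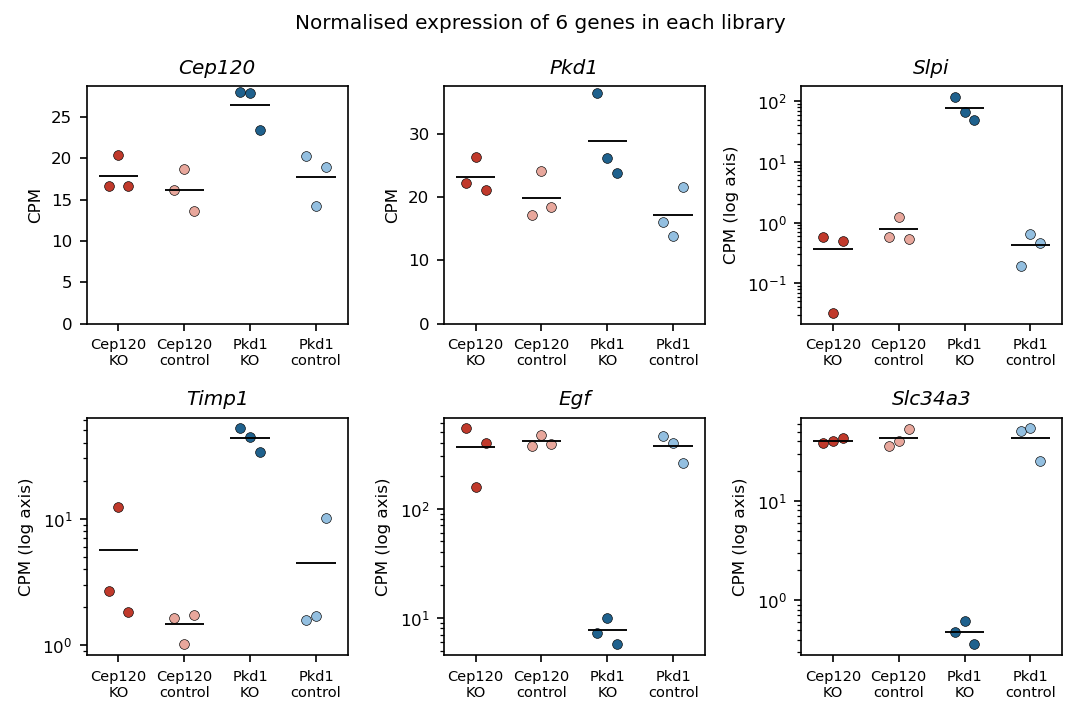
CPM of the targeted genes Cep120 and Pkd1 (linear axes from 0) and of Slpi, Timp1, Egf and Slc34a3 (log axes) in each library by group, with dots for libraries and lines for group means. Slpi averaged 78.1 CPM in Pkd1 KO against 0.434 in Pkd1 controls, and Egf 7.68 against 373.

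Libraries differed in 2 further ways, in genes detected, which follow the line except in replicate 3 of each control group, and in sex-linked RNA, which follows the groups in part. Cep120 KO 1 to 3, Cep120 controls 1 and 2 and Pkd1 control 3 had 30321 to 32740 genes with a count above 0, and the other 6 libraries had 23544 to 25665. Xist, the RNA of the inactive X chromosome, was under 1 CPM in Cep120 KO 1 and 2 and in all Pkd1 KO libraries, and 53.6 to 193 CPM in the other 7. All Pkd1 KO libraries therefore lacked Xist and all Pkd1 controls had it, and Pkd1 control 3 also had 104 CPM of Y-linked RNA.

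**Figure D2:**
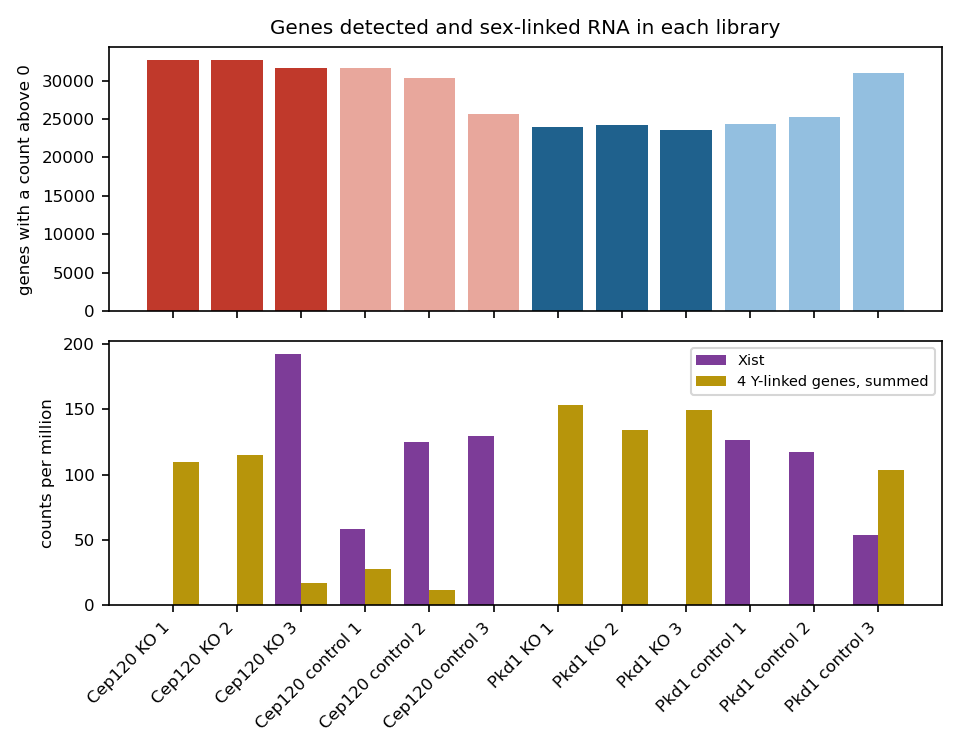
Upper bars give the genes with a count above 0 in each library, and lower bars give CPM of Xist and the sum of 4 Y-linked genes. Cep120 control 3 has 25665 genes detected and Pkd1 control 3 has 31031, each on the side of the other line.

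The Cep120 comparison asks which pathways change in kidneys after Cep120 loss from the ureteric lineage. Genes of fibrillar collagen and matrix were higher as a list in the libraries labelled Cep120 KO, with a median log2 fold change of 0.48 and 20 of 23 members above 0. Lymphocyte, intercalated cell, principal cell, loop of Henle, cell cycle, fatty acid oxidation and adipose tissue lists were lower, and none of the 8 lists passed with an estimated correlation (adjusted p = 0.817 for each). The matrix score was 0.79 in Cep120 KO 2 but -0.20 in Cep120 KO 1 and 0.08 in Cep120 KO 3, against -0.30 to -0.08 in the controls. The changes were small beside the spread between libraries, and no single gene passed the test. Col1a1, a fibrillar collagen chain, had a log2 fold change of 0.93 (SE 0.36, adjusted p = 0.757), and Fn1, fibronectin, one of 0.64. Timp1, an inhibitor of matrix proteases, was at 12.4 CPM in Cep120 KO 2 but at 2.69 and 1.85 in Cep120 KO 1 and 3, against 1.02 to 1.74 in the controls. Havcr1, which marks injured proximal tubule, was at 12.7 CPM in Cep120 KO 2 and at 2.54 and 0.248 in Cep120 KO 1 and 3.

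Of 19890 genes tested, edgeR called 0 between Cep120 KO and its controls. The unadjusted p was under 0.05 for 1201 genes where 994.5 would be by chance, voom called 0, and DESeq2 called 19, of which 7 were higher and 12 lower. The DESeq2 calls included Cd8a, a T cell coreceptor, at -1.88 (adjusted p = 0.0232) and Mb, myoglobin, at -3.75 (adjusted p = 7.36e-05). In edgeR Cd8a was at 0.918 ± 0.232 CPM in KO and 3.36 ± 0.538 in control libraries (log2 fold change -1.87, SE 0.38, adjusted p = 0.630). Adjusted over the list alone, Cd8a fell in the T and B cell list and Mb fell in the skeletal muscle list, and no member of any other list passed.

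The list test called 8 of 32 lists for Cep120 KO. The fibrillar collagen and matrix list was higher (adjusted p = 0.00493, and 0.817 with an estimated correlation). The lower lists, each also at 0.817 with an estimated correlation, were intercalated cell (median -0.42, adjusted p = 0.000144), T and B cell (-0.61, 0.000913), adipose tissue (-1.62, 0.000913) and cell cycle (-0.18, 0.00499). Principal cell (-0.16), loop of Henle (-0.20) and fatty acid oxidation (-0.15) were also lower, each with an adjusted p of 0.0129. Intercalated cell members included Foxi1, their main transcription factor, at -0.47 and Rhbg, an ammonia transporter, at -0.62, and principal cell members included Scnn1b, an epithelial sodium channel subunit, at -0.31. None of these 3 genes passed alone. The adipose score of Cep120 KO 1 and 2 was -4.71 and -4.70, against -0.24 to 0.32 in the controls, and these are the Cep120 libraries that lacked Xist. Among the Pkd1 KO libraries, which all lacked Xist, it was -5.38 in Pkd1 KO 2 but 1.36 and 0.21 in Pkd1 KO 1 and 3.

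The matrix call for Cep120 KO ended without Cep120 KO 2 (adjusted p = 0.541) and without Cep120 control 1 (0.0832), and its adjusted p was 0.235 to 0.730 with any of 6 sex terms in the fit. Under those terms 3 or 4 lists were called, and the T and B cell list was the only one of the 8 called under all 6 (the intercalated cell list was called under Xist absent or present alone). With Xist presence as a term, the Cep120 comparison rests on Cep120 KO 3 alone against the controls. T and B cell scores overlapped between the groups, at 0.19, -0.91 and -0.57 in Cep120 KO 1 to 3 and 0.58, 0.54 and -0.36 in Cep120 controls 1 to 3. The cell cycle call ended without Cep120 KO 1 (0.117) or Cep120 control 3 (0.0577), the loop of Henle call without Cep120 KO 2 (0.476) or Cep120 control 3 (0.150), and the fatty acid oxidation call without Cep120 KO 2 (0.476) or Cep120 control 2 (0.0852). The cell cycle, principal cell and loop of Henle calls ended with the detected-gene class as a term (0.0710, 0.0694 and 0.287) and without both replicate 3 controls (0.0645, 0.0510 and 0.113).

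The other 24 lists were not called for Cep120 KO. Their medians and adjusted p were 0.16 and 0.248 for myofibroblast and stromal cell, 0.44 and 0.418 for tubular injury, 0.44 and 0.158 for chemokine, cytokine and complement, 0.13 and 0.0917 for YAP and TAZ targets, and 0.20 and 0.384 for the TGF-beta and BMP pathway. Signalling and structural lists gave 0.06 and 0.520 for the Hedgehog pathway, 0.06 and 0.620 for p53 targets, 0.06 and 0.384 for centrosome and cilium, and 0.27 and 0.158 for immediate early genes. Renin and angiotensin gave -0.42 and 0.0560, skeletal muscle -0.18 and 0.0560, distal convoluted tubule 0.09 and 0.563, and podocyte 0.08 and 0.620. Macrophage, neutrophil, Wnt target, Notch, ureteric bud tip, nephron progenitor, proximal tubule, endothelial cell, red blood cell, adrenal and urothelium medians lay between -0.11 and 0.03, with adjusted p from 0.325 to 0.861. With the deposited log2 CPM all of these medians but that of Notch changed sign, but the median of all genes also moved, from 0.01 to 0.15, and relative to it none changed side. The median, mean and test differed in sign for macrophage, Notch, ureteric bud tip, adrenal and urothelium genes.

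**Figure D3:**
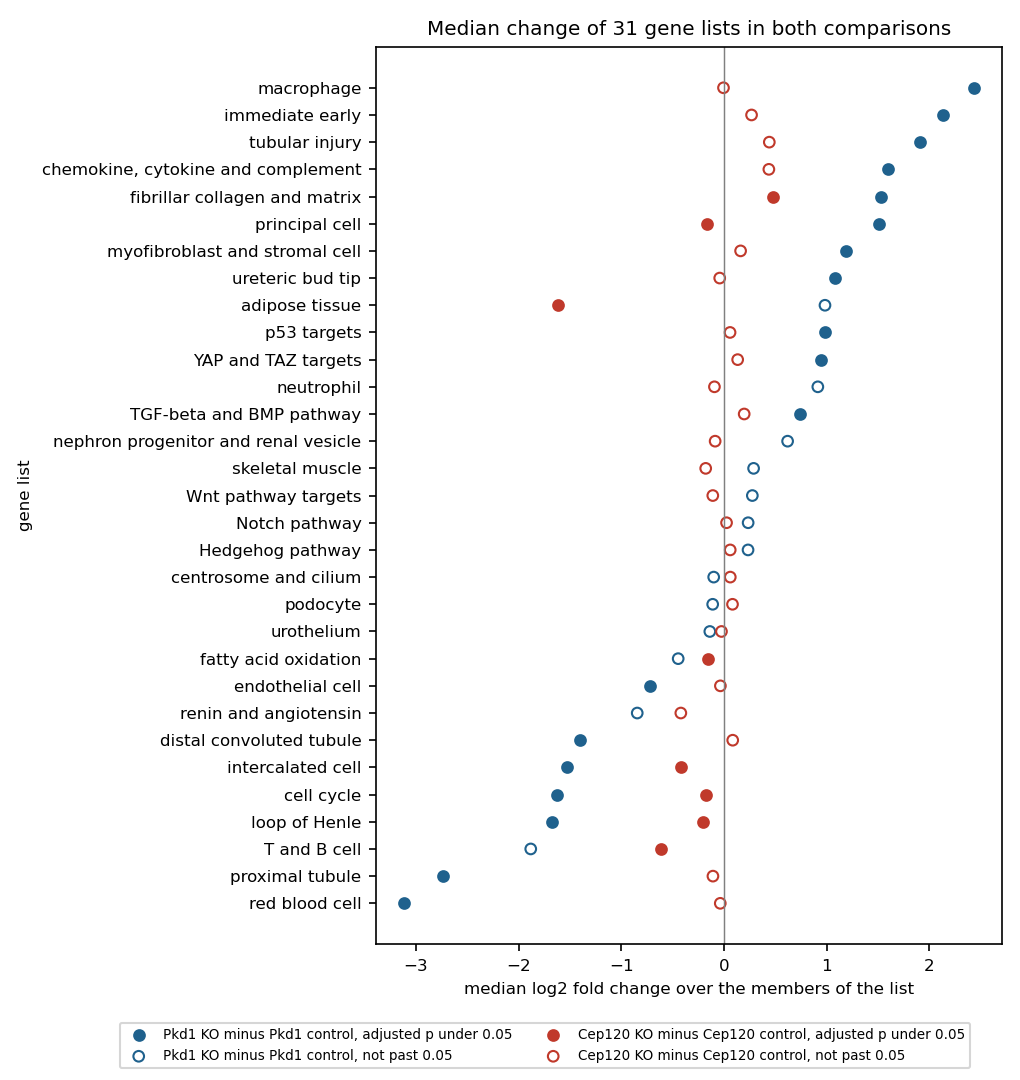
Median log2 fold change over the members of each gene list, for Pkd1 KO minus Pkd1 controls (blue) and Cep120 KO minus Cep120 controls (red), filled where the camera test at a preset correlation gave an adjusted p under 0.05. Macrophage (2.43) and red blood cell (-3.11) are the ends for Pkd1, the adrenal list is left out because 1 library carries it, and the not called adipose median of Pkd1 changes sign with the deposited log2 CPM.

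The Pkd1 comparison sets a ciliary cystic model beside Cep120. In the libraries labelled Pkd1 KO, lists of tubular injury, matrix, myofibroblast and macrophage genes were higher, and lists of proximal tubule, loop of Henle and distal convoluted tubule genes lower. None of these lists passed with an estimated correlation (adjusted p from 0.183 to 0.410). Slpi (ENSMUSG00000017002), a secreted protease inhibitor, rose from 0.434 ± 0.229 CPM to 78.1 ± 36.3 (SD, n = 3), 188-fold by the fitted log2 fold change of 7.56 (SE 0.57, edgeR adjusted p = 1.49e-06). Slc34a3 (ENSMUSG00000006469), a proximal tubule phosphate transporter, went from 43.4 ± 15.7 CPM to 0.482 ± 0.127, a log2 fold change of -6.47 (SE 0.34, adjusted p = 1.71e-07). Egf (ENSMUSG00000028017), made in the thick ascending limb and distal convoluted tubule, went from 373 ± 102 CPM to 7.68 ± 2.15, a log2 fold change of -5.60 (SE 0.43, adjusted p = 1.78e-06). Among the largest rises were also Adh7 (6.70, SE 0.62), Hp, haptoglobin (6.04, SE 0.86), Fcgbp (5.55, SE 0.31) and Apod (5.40, SE 0.80). Among the largest falls were Pvalb, parvalbumin of the distal convoluted tubule (-7.97, SE 0.56), Slc22a7 (-6.39, SE 0.68), Mro (-5.10, SE 0.52) and Aspdh (-5.07, SE 0.41). Saa3 (6.67), Lgals7 (5.47) and Slc22a30 (-4.96) were also named by the rule, but each shares sequence with close copies, and their values are uncertain.

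Of 19890 genes tested, edgeR called 8839, which is 44.4%, with 4388 higher and 4451 lower in the libraries labelled Pkd1 KO. Of these, 1970 rose and 2618 fell at least 2-fold. The balance depends on scaling, with 3779 higher and 5095 lower under upper quartile factors and 4930 higher and 3810 lower with the deposited log2 CPM. The count was 5256, 4337 or 2002 with sex as a term in 3 codings, and the 5256, 4337 and 2002 contain 54.3%, 44.6% and 22.4% of the 8839 in the same direction. In the Pkd1 line absence of Xist and the KO label coincide in every library. Y-linked RNA was at 104 CPM in Pkd1 control 3, which also carries Xist, and at 0.0628 and 0.0433 in Pkd1 controls 1 and 2. Within the line the sex share codings thus drew mainly on that library, which is also in the other detected-gene class. Sex and genotype can therefore not be separated within the Pkd1 line. With Xist presence as a term, the sex effect was taken from Cep120 KO, the only group in which Xist presence varied. Of 130 named genes called, 79 kept their call in every alternative.

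Nephron segment genes fell together in the libraries labelled Pkd1 KO. All 20 proximal tubule genes fell, with a median log2 fold change of -2.74 (adjusted p = 3.91e-13, and 0.183 with an estimated correlation). Examples are Cubn, an endocytic receptor (-2.76, SE 0.15), Slc22a8, an organic anion transporter (-2.96, SE 0.15), and Miox (-4.75, SE 0.33). Of 12 loop of Henle genes 9 fell and Slc14a2, a urea transporter, rose by 1.68 (list median -1.68, adjusted p = 0.000528, and 0.392 with an estimated correlation). Umod, uromodulin, changed by -1.37 and Cldn10 by -2.45. Of 10 distal convoluted tubule genes 9 fell, with a median of -1.40 (adjusted p = 2.63e-05, and 0.183 with an estimated correlation). Slc12a3, the thiazide-sensitive cotransporter, changed by -2.43 (SE 0.12).

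Collecting duct genes went both ways. Of 14 principal cell genes 11 rose and 3 fell (median 1.51, adjusted p = 0.000684, and 0.183 with an estimated correlation). Scnn1b rose by 2.16 (SE 0.11) to 329 CPM from 73.5, Gata3 by 1.91 and Aqp2, the water channel under vasopressin control, by 2.51 (adjusted p = 0.00729). Tfap2b, Hsd11b2 and Hoxd8 are the 3 that fell, Tfap2b with a log2 fold change of -1.20. Of 13 intercalated cell genes 9 fell and 2 rose (median -1.53, adjusted p = 0.00464, and 0.478 with an estimated correlation). Slc26a4, pendrin, changed by -4.23 and Slc4a1 by -3.08, while Foxi1 rose by 0.92 and Rhcg by 1.02. Of 11 ureteric bud tip genes 6 rose and 1 fell (median 1.08, adjusted p = 0.0152, and 0.183 with an estimated correlation), or 7 and 1 adjusted over the list alone. Wnt7b rose by 2.01 and Wnt9b by 2.31, and Slco4c1 changed by -2.02. The intercalated cell call ended with the sex share as a term (adjusted p = 0.0937), as did that of the bud tip list, which also ended under the stricter filter (0.102).

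Matrix, stromal and injury genes rose in the libraries labelled Pkd1 KO. Of 23 matrix genes 19 rose and 0 fell (median 1.53, adjusted p = 2.37e-07, and 0.380 with an estimated correlation), or 20 and 0 adjusted over the list alone. Lox, which cross-links collagen, rose by 2.54 (SE 0.20), Mmp2 by 1.81 and Col12a1 by 4.57. Of 14 myofibroblast and stromal cell genes 13 rose (median 1.19, adjusted p = 4.54e-06, and 0.187 with an estimated correlation), among them Cnn1, calponin, by 3.52 (SE 0.28). Acta2, smooth muscle actin, rose from 232 to 1774 CPM, a call that ended with the scaled sex share and class as terms. Of 15 tubular injury genes 12 rose and 1, Hopx, fell (median 1.92, adjusted p = 5.10e-05, and 0.410 with an estimated correlation). Lgals3 rose by 2.33 (SE 0.16), Krt20 by 4.39, Krt18 by 2.77 and Lcn2, which tubules secrete after injury, by 4.57, from 40.7 ± 38.1 CPM to 965 ± 114. Matrix and injury scores were also raised in Pkd1 control 3, at 0.69 and 0.98, against -0.10 in Pkd1 control 2 for matrix and -0.45 and -0.32 in Pkd1 controls 1 and 2 for injury. Pkd1 control 3 lay on the KO side of both Pkd1 controls 1 and 2 for every list called except principal cell and endothelial cell. Raised scores were myofibroblast (0.35 against -0.08 and -0.02), immediate early (0.75 against -0.14 and -0.34), ureteric bud tip (0.40 against -0.28 and -0.31), YAP and TAZ (0.39 against -0.06 and -0.04), TGF-beta and BMP (0.44 against -0.04 and -0.14) and p53 (0.16 against -0.09 and -0.11). Lowered scores were intercalated cell (-0.61 against 0.10 and 0.14), loop of Henle (-0.45 against 0.22 and 0.11), proximal tubule (-0.34 against 0.19 and 0.21), distal convoluted tubule (-0.06 against 0.12 and 0.01), red blood cell (-0.29 against 0.14 and 0.11) and cell cycle (-0.26 against -0.08 and -0.06).

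Macrophage and chemokine genes rose in the libraries labelled Pkd1 KO. Of 15 macrophage genes 14 rose and 0 fell (median 2.43, adjusted p = 5.10e-06, and 0.392 with an estimated correlation). Csf1r, the macrophage growth factor receptor, rose by 1.74, Cd68 by 2.80 and C1qc by 2.70, and these 3 calls ended with Xist presence as a term, at 1.28 (SE 0.37), 1.79 (SE 0.66) and 1.88 (SE 0.72). Over all alternatives their log2 fold changes went down to 1.08, 1.503 and 1.52. Of 17 chemokine, cytokine and complement genes 10 rose (median 1.60, adjusted p = 0.00135, and 0.478 with an estimated correlation), or 11 adjusted over the list alone, and the list call ended with 5 of 6 sex terms (0.245 with the sex share). Il34 and Csf1, both ligands of Csf1r, rose by 2.95 and 2.09, calls that also ended with Xist presence as a term, at 2.10 (SE 0.70) and 1.21 (SE 0.52). Macrophage and chemokine scores were raised in Pkd1 control 3 too, at 0.81 and 1.27, against -0.85 and -0.93 in Pkd1 control 1, -0.50 and -0.57 in Pkd1 control 2, and 1.99 to 2.52 and 1.66 to 1.87 in Pkd1 KO. Of 12 T and B cell genes 7 fell and 1 rose, but the list did not pass (median -1.88, adjusted p = 0.0709). Cd8a changed by -4.73 and Ms4a1, a B cell surface protein, by -5.72. Neutrophil genes did not pass as a list (1 rose and 1 fell of 8, median 0.92, adjusted p = 0.244).

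Cell cycle genes fell, and p53 target and immediate early genes rose, in the libraries labelled Pkd1 KO. Of 20 cell cycle genes 19 fell and 0 rose (median -1.62, adjusted p = 2.39e-10, and 0.216 with an estimated correlation). Cenpf, a mitotic kinetochore protein, changed by -2.35 (SE 0.15), Birc5 by -2.34 and Top2a by -2.29. Of 18 p53 targets 14 rose (median 0.98, adjusted p = 3.37e-05, and 0.183 with an estimated correlation), or 15 with 1 falling adjusted over the list alone. Cdkn1a, which blocks cell cycle kinases, rose from 47.2 ± 2.54 CPM to 199 ± 2.61, by 2.08 on the log2 scale (SE 0.14). All 12 immediate early genes rose (median 2.13, adjusted p = 4.26e-06, and 0.183 with an estimated correlation), Nr4a1 among them by 2.44. Of 18 TGF-beta and BMP pathway genes 10 rose and 2 fell (median 0.74, adjusted p = 0.00464, and 0.183 with an estimated correlation). Tgfb3 rose by 3.13 and Inhba, an activin subunit, by 3.40, while Tgfb1 stood at 0.06. Of 14 YAP and TAZ targets 8 rose and 0 fell (median 0.95, adjusted p = 5.10e-05, and 0.183 with an estimated correlation), among them Ccn1 by 2.97 and Amotl2 by 1.37.

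Vessel and blood genes fell. Of 12 endothelial cell genes 10 fell and 0 rose (median -0.72, adjusted p = 0.000205, and 0.245 with an estimated correlation), Flt1, a receptor for vascular growth factor, by -1.01. Of 8 red blood cell genes 7 fell (median -3.11, adjusted p = 0.000201, and 0.187 with an estimated correlation). Alas2, which starts haem synthesis in red cells, changed by -2.75 and Hba-a2 by -3.13, although globin copies share reads and their split is uncertain.

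Several pathway and cell type lists did not pass for Pkd1 KO. Of 14 Wnt targets 6 rose and 4 fell (adjusted p = 0.191), with Nkd1 at 1.67 and Notum at -2.84. Of 14 Hedgehog pathway genes 5 rose and 1 fell (0.168), and Gli1, at 2.14, lost its call with every sex term. Notch pathway genes had 3 of 14 rising (0.301), or 2 adjusted over the list alone. Centrosome and cilium genes had 2 rising, the targeted genes themselves, and 5 falling of 26 (0.546), or 2 and 1 adjusted over the list alone, and both rises lost their call with every sex term. Nephron progenitor and renal vesicle genes had 5 rising and 3 falling of 11 (0.756), with Wnt4 at 1.75 and Cited1 at -2.40. Podocyte genes had 2 rising and 4 falling of 12 (0.284), with Cdkn1c at -2.71. Fatty acid oxidation genes had 3 rising and 8 falling of 16 (0.0891), with Ppargc1a at -1.51. Renin and angiotensin genes had 1 rising and 4 falling of 10 (0.0626), with Agtr2 at 3.78 and Ace at -2.34. Urothelium genes had 1 rising and 1 falling of 10 (0.676), with Upk3b at 2.63.

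Markers of tissue next to the kidney varied between libraries. All 5 measured adrenal genes passed, but Cyp11b1, an adrenal cortex enzyme, was at 438 CPM in Pkd1 KO 3, at 0.711 and 0.902 in Pkd1 KO 1 and 2, and at 0 in the Pkd1 controls. Star, also of the adrenal cortex and 1 of the 8 largest rises, was at 269 CPM in Pkd1 KO 3 and at 3.11 and 2.64 in Pkd1 KO 1 and 2, its call ended without Pkd1 KO 3 and with each of 6 sex terms, and the adrenal list did not pass (adjusted p = 0.193). Ucp1, the uncoupling protein of brown fat and 1 of the 8 largest falls, was at 7.48, 0.161 and 1.11 CPM in Pkd1 KO and at 184, 239 and 27.8 in Pkd1 controls, and its call ended without Pkd1 KO 2, Pkd1 KO 3 or Pkd1 control 2 and with the sex share as a term, while its log2 fold change turned positive, up to 2.94, with the other 5 sex terms. The adipose list had 2 members rising and 1 falling of 10, or 1 and 1 adjusted over the list alone, with a median of 0.99 and a mean of 0.21 while the test pointed lower (0.756). The skeletal muscle list had 1 rising and 1 falling of 4, with a median of 0.29 and a mean of -1.46 (0.756), and the gene that fell is Pvalb.

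The difference between the effects, the Cep120 change minus the Pkd1 change, tests which genes changed differently in the lines. A gene can pass it through its Pkd1 change alone, and edgeR called no gene for Cep120 KO. Lists of proximal tubule, loop of Henle and distal convoluted tubule genes stood higher, and myofibroblast and macrophage lists lower, in the Cep120 change than in the Pkd1 change, both read from the labels. None of these lists passed with an estimated correlation (adjusted p from 0.207 to 0.468). Pvalb differed by 8.03 (SE 0.66, edgeR adjusted p = 1.46e-05) and Slc34a3 by 6.38 (SE 0.41, adjusted p = 3.10e-06). Fcgbp differed by -6.05 (SE 0.41), Hp by -6.85 (SE 1.12), Adh7 by -5.86 and Il18r1, a cytokine receptor, by -5.20. Scnn1b, which had opposite signs in the comparisons, differed by -2.48, and Cenpf by 2.18. In all 5598 genes passed, 2834 higher and 2764 lower.

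Lists of the difference were called in 17 cases. Higher were proximal tubule (18 of 20 members, 0 lower, adjusted p = 2.72e-13), cell cycle (16 of 20, 8.60e-09), distal convoluted tubule (9 of 10, 2.33e-05), red blood cell (7 of 8, 0.000398), endothelial cell (6 of 12, 0.00100) and loop of Henle (8 of 12 with 1 lower, 0.00299). Lower were matrix (12 of 23, 2.33e-05), immediate early (9 of 12, 2.33e-05), macrophage (12 of 15, 1.98e-05), myofibroblast (9 of 14, 2.74e-05), principal cell (10 of 14 with 2 higher, 0.000101) and p53 targets (7 of 18, 0.000101). Tubular injury (6 of 15, 0.000320), YAP and TAZ targets (6 of 14, 0.000794), TGF-beta and BMP pathway (4 of 18 with 1 higher, 0.00931), ureteric bud tip (4 of 11 with 1 higher, 0.0114) and chemokines (5 of 17, 0.0127) were also lower. With an estimated correlation the adjusted p of these 17 lists ran from 0.207 to 0.659. The chemokine and bud tip calls ended under the stricter filter (0.0713 and 0.141), and the chemokine call also with the scaled sex share as a term (0.105) and by fry (0.158).

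The control groups, set against each other to see how far line alone separates them, showed no gene past the test. Cep120 stood at -0.14 and Pkd1 at 0.21 between them. The edgeR fit called 0 of 19890 genes with 834 at an unadjusted p under 0.05, and DESeq2 and voom called 0. Without Cep120 control 3 and Pkd1 control 3 together, 371 genes passed, and without Pkd1 control 3 alone 4 passed, the pseudogenes Atp6v0c-ps2, Rps2-ps10 and Rnps1-ps and the predicted gene Gm18736.

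Overlap was tested in each direction, and no library is shared between the Cep120 and Pkd1 comparisons. No gene was called in both, since edgeR called 0 for Cep120. With Cep120 genes taken instead at an unadjusted p under 0.05, 181 of 653 higher genes were also called higher for Pkd1, where 144.1 would be by chance (Fisher's exact test, one-sided, p = 0.00032). Of 548 lower genes 124 were called lower for Pkd1, where 122.6 would be by chance (one-sided exact test, p = 0.460). Both exact tests treat genes as independent draws, which genes measured in the same libraries are not. Xist was absent from Cep120 KO 1 and 2 and from all Pkd1 KO libraries but from no control, so the overlap was not separated from sex. Across the 19890 genes, which are not independent replicates, the log2 fold changes had a Pearson r of -0.079 and a Spearman rho of -0.015. The sign of r changed under the stricter filter (0.180), without Pkd1 control 3 (0.078), without both replicate 3 controls (0.044) and with each of the 5 sex terms tried for it. A sex term fits the same sex effect of a gene in both lines. The comparisons are then no longer separate, so r under those 5 terms cannot show whether the lines changed alike.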

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

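Tests of exchanged labels, of a library batch, of sex and of the replicate 3 controls were chosen only after the results were seen, and those of depth, adrenal RNA, power and other splits before.

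Each value here is the Cep120 change minus the Pkd1 change on the log2 scale, and each is given because an edgeR test, or for lists camera, of that difference between the lines passed its threshold. Every direction rests on the KO labels, since neither targeted gene was lower in them. In all 5598 genes passed. Tubule and transport genes with positive differences were Pvalb (8.03), Slc34a3 (6.38), Slc22a7 (5.76), Egf (5.42), Slc22a8 (2.99) and Slc12a3 (2.65). Slc22a28 (5.66) and Hba-a2 (3.50) also had positive differences, but share reads with close copies. Cenpf, a mitotic gene, differed by 2.18 and Flt1, an endothelial receptor, by 0.89. Negative differences included Hp (-6.85), Fcgbp (-6.05), Adh7 (-5.86) and Il18r1 (-5.20). Stromal and injury genes among them were Cnn1 (-3.25), Lgals3 (-2.55) and Lox (-2.43), and signalling genes were Tgfb3 (-2.59), Cdkn1a (-2.34), Nr4a1 (-2.18), Wnt7b (-2.18) and Amotl2 (-1.47). Scnn1b differed by -2.48, Csf1r by -1.62 and Cxcl16 by -1.11.

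Lists whose members stood higher in the Cep120 change had median differences of 3.22 for red blood cell, 2.72 for proximal tubule, 1.502 for distal convoluted tubule, 1.49 for cell cycle, 1.396 for loop of Henle and 0.76 for endothelial cell. Lists on the other side were macrophage (-2.19), principal cell (-1.73), immediate early (-1.54), chemokine, cytokine and complement (-1.40), myofibroblast and stromal cell (-1.38), tubular injury (-1.24) and matrix (-1.14). Ureteric bud tip (-0.93), YAP and TAZ targets (-0.85), p53 targets (-0.83) and the TGF-beta and BMP pathway (-0.38) were also lower. With an estimated correlation none of these 17 lists passed, with adjusted p from 0.207 to 0.659.

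The first pattern is that replicate 3 of each control group sits with the libraries of the other line, with Rpl34-ps1 at 207 CPM in Cep120 control 3 but at 6.27 to 7.85 in the other Cep120 libraries, and at 7.63 in Pkd1 control 3 but at 107 to 212 in the other Pkd1 libraries. Depth as the cause is argued against, since the gap in detected genes between the classes was 4656 before and 4699 after every library was thinned to 23070688 counts. Exchanged labels stay open, because the test could not decide. Of the 486 genes that separate the other 5 libraries of each line, 75.1% place both with the other line. The bound for an exchange also asked that both libraries keep the detected-gene totals of their own line. Neither did, so no share could have met that bound. Of the 486 genes 470 were higher in the Cep120 line, whose other 5 libraries had more genes detected, so the share was not separated from the detected-gene class. A library or sequencing batch stays open too, because both of the 2 libraries lie outside the range of their own line in detected genes while 1 lies inside that of the other line, and the labels name no batch. These cannot be told apart here, and no biological explanation was tested.

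The second pattern is the breadth of the Pkd1 KO difference, 8839 genes. Adrenal RNA in Pkd1 KO 3 and the detected-gene class of Pkd1 control 3 are argued against as the whole cause, since 84.1% of these genes were called in the same direction without Pkd1 KO 3 and 89.2% without both replicate 3 controls. Sex of the animals is argued against as the whole cause too, since over these genes Cep120 KO 1 and 2, which also lack Xist, were shifted from the Cep120 libraries with Xist by a median of 3.003% and 10.9% of the Pkd1 KO change (SD of those libraries 5.12%). Pkd1 control 3, with 104 CPM of Y-linked RNA, was shifted by 17.3% from the other Pkd1 controls. That shift decides nothing, since this library was among the controls by which these genes were chosen and it also carries Xist. Sex as part of the cause cannot be told apart from genotype within the Pkd1 line, as 54.3%, 44.6% or, at the lowest of 3 codings, 22.4% were called again with sex as a term. The median size of the log2 fold change went from 1.05 to 0.87, 0.84 and 0.91 and the median SE from 0.193 to 0.253, 0.276 and 0.350. Sizes fell and errors grew, and their shares in the lost calls were not separated. Loss of Pkd1, which the labels name, stays open as a hypothesis, and what sex adds to it was not separated.

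The third pattern is that no gene was called by edgeR between Cep120 KO and its controls, while 1201 had an unadjusted p under 0.05, voom called 0 and DESeq2 19. Cep120 control 3 in the other detected-gene class stays open. Leaving out both replicate 3 controls gave 1 gene, Gm4737, which met the bound set against it. That fit had 1407 of 20591 genes at an unadjusted p under 0.05 and a median SE of 0.224 against 0.216. With fewer controls and a larger error, few calls cannot exclude that this library hid changes. Sex of the animals stays open as what hid changes, since 3 codings of sex as a term gave 0 genes but also weaker fits, with 624, 625 and 513 genes at an unadjusted p under 0.05 and a median SE of 0.252, 0.252 and 0.310 against 0.216. Too little power at 3 libraries a group stays open: 89.4% of simulated 4-fold changes were recovered, which passed the bound set beforehand against it, but a bound from simulated settings excludes nothing, and 54.6% of 2-fold and 8.51% of 1.5-fold changes were recovered. A small effect of Cep120 loss on whole-kidney RNA was not tested apart from these.

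Other splits of the libraries into 3 and 3 are 10 for each comparison of 2 groups, too few for a share under 0.05. For Cep120 KO the real split gave 0 genes, so all 10 gave as many, and the highest other gave 81, with Cep120 KO 1 and controls 1 and 2 on one side. For Pkd1 KO the real split gave 8839 genes, the only 1 of 10 to reach it, and the highest other gave 0. Between the control groups the real split gave 0 and all 10 gave as many. The highest other gave 1879, in the split that follows the detected-gene classes. That split also separates the controls with Y-linked RNA at 11.7 to 104 CPM from those at 0 to 0.0628. Exchanged replicate 3 labels would give it too, so the 1879 genes do not tell these apart. For the difference, 6 of 100 regroupings within the lines gave at least 5598 genes, the real one included, and the highest other gave 6077, so chance is not excluded by this count. The 10 drawn that left the Pkd1 groups in place gave 4816 to 6077 genes, and the 89 that mixed them gave at most 14. The number of genes thus followed the grouping of the Pkd1 libraries, and it gives no evidence of an effect of Cep120 KO.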

How the results depend on the processing

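Terms for sex and for the detected-gene class, and the fit without both replicate 3 controls, were chosen after seeing the data. Cep120 KO gave 0 genes, and 19 by DESeq2 (7 higher), 344 with no filter (171 higher), 1 (Gm4737) without both replicate 3 controls and 3 (Serpina3g, Gm47283 and E030030I06Rik) with Xist presence and class as terms. Leaving out 1 library gave 0 to 2, with Gm8615 without Cep120 KO 2, Aldh1a3 and Xist without Cep120 KO 3, and Gm4737 without Pkd1 control 3. Pkd1 KO gave 8839 genes, and 5256, 4337 and 2002 with the sex share, the share scaled to Pkd1 KO and Xist presence as terms. With class added these were 3378, 2546 and 3642. Other settings gave 6941 (stricter filter) to 10499 (pooled controls), and leaving out 1 library 7277 to 9266. The difference gave 5598, and 3502 with the scaled share and class as terms. With upper quartile scaling 60.7% of its calls were higher against 50.6%, as the median of all genes moved from 0.06 to 0.17. That median moved for Cep120 from 0.01 to 0.15 with the deposited log2 CPM, and for Pkd1 from -0.04 to -0.13 with upper quartile scaling, where 42.6% of its calls were higher, against 49.6% in the fit reported and 56.4% with the deposited log2 CPM. Controls against each other gave 0 genes, 248 with no filter, 371 without both replicate 3 controls, 1 with the sex share and 1 with the scaled share (Atp6v0c-ps2), and 1 with class (Gm10503). Sex share with class and scaled share with class gave 2 each, those same genes. Leaving out 1 library gave 0 to 4. Overlap was 0, and 5 by DESeq2 with 6 in opposite directions, 1 without both replicate 3 controls, 2 with Xist presence and class as terms, and 0 to 2 leaving out 1 library.

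Lists called for Cep120 were 8, and 4 with the sex share, 4 with the scaled share, 3 with Xist presence, and 4 with class added to any of these, 6 with class alone and 8 without both replicate 3 controls, each of these last keeping 5 of the 8, 0 with an estimated correlation, 0 by fry and 6 to 12 leaving out 1 library. For Pkd1 18 were called, 16, 16 and 19 with the 3 sex codings, 26 by fry and 0 with an estimated correlation, and for the difference 17, with 17 by fry, 16 of them shared, 16 with the scaled share and 0 with an estimated correlation. The loop of Henle list turned higher for Cep120 with the sex share (adjusted p = 0.649), that and class (0.796), the scaled share (0.719), that and class (0.871) and Xist presence with class (0.826). The adipose list did so with Xist presence and class (0.833). For Pkd1 the log2 fold change of Ucp1 was -5.68 and became 1.27 with sex share and class, 0.026 with the scaled share, 2.33 with that and class, 2.94 with Xist presence and 2.73 with that and class. Chgb turned to -1.60 without Pkd1 KO 3, the library that carries adrenal RNA, in a range up to 8.66 leaving out 1 library. Cyp11b1 gave -34.28 with the scaled share and -138.19 with class added, fits that cannot be estimated because its Pkd1 controls are at 0. Apart from Cyp11b1 and Chgb the cause was not tested. A block on replicate number left 7804 genes for Pkd1, 4363 for the difference and 0 for Cep120. Limiting the fit to the libraries of 1 comparison was not run for the difference, which needs all 12. Totals of 23070736 to 31837973 counts limit the weakest genes.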

Other observations

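Gene families and the pattern genes of single libraries were chosen after the data were seen, and the values below are reported without an explanation.

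Mitochondrial energy genes and ribosomal protein genes moved apart in the libraries labelled Pkd1 KO, where families sharing the letters of their symbols were tested with camera over 199 families. Of 26 Cox genes, most of them subunits or assembly factors of cytochrome oxidase, 21 fell and 1 rose, with a median log2 fold change of -1.08 (adjusted p = 4.68e-05). All 11 Ndufb and 13 of 14 Ndufa genes, subunits of respiratory complex I, fell, with medians of -1.14 and -0.96. Mitochondrial ribosome genes fell too, 29 of 49 in the Mrpl family and 18 of 29 in the Mrps family. Of 50 Rpl genes of the cytosolic ribosome 33 rose and 0 fell (median 0.50), and of 46 Rps genes 33 rose and 2 fell (median 0.59). Many ribosomal protein genes have processed copies that share reads, so their values are uncertain. None of these families passed with an estimated correlation, where the adjusted p was 0.737 to 0.790. RNA of the mitochondrial genome was 3.14 to 3.47% of counts in Pkd1 KO and 4.78 to 9.14% elsewhere.

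Other families of the Pkd1 comparison included annexins, of which 9 of 10 rose, and Toll-like receptors, of which 8 of 11 rose. Kallikreins (8 of 10), carbonic anhydrases (9 of 14) and Kcnj potassium channels (8 of 11) fell. With an estimated correlation the adjusted p of each was 0.737. For Cep120 KO the medians were -0.29 for Rpl, -0.26 for Rps and -0.30 for Cox with no single gene past the test. Camera at the preset correlation gave them adjusted p of 2.33e-16, 1.16e-07 and 2.23e-05, and with an estimated correlation the adjusted p was 0.856. The directions named for Pkd1 were the same under TMM, RLE, upper quartile and deposited scaling.

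Some genes followed the detected-gene classes or cut across the groups. Abhd1 was at 37.1 to 68.0 CPM in the 6 libraries with more genes detected and 1.96 to 2.66 in the other 6, and Tmem87a at 27.5 to 46.6 and 3.27 to 5.68. Olfactory receptor genes detected, of 1103, were 522 to 704 and 33 to 229, with 587 in Pkd1 control 3 and 201 in Cep120 control 3. For Pkd1 KO 25 of 78 Olfr and 17 of 56 Vmn genes fell and 0 rose, with medians of -4.39 and -4.35. Their camera adjusted p was 0.00567 and 0.00913, and 0.840 and 0.845 with an estimated correlation. For Cep120 KO the Olfr and Vmn medians were 0.61 and 0.54 (camera adjusted p = 3.16e-06 and 3.13e-05, and 0.856 with an estimated correlation). H2-K1, a class I histocompatibility gene with close copies, was at 773, 838 and 878 CPM in Cep120 KO 1 and Cep120 controls 1 and 2, and at 137, 175 and 162 in Cep120 KO 2, Cep120 KO 3 and Cep120 control 3. Xist and Y-linked RNA were both present in 4 libraries, at 53.6 and 104 CPM in Pkd1 control 3, 58.7 and 27.7 in Cep120 control 1, 193 and 17.4 in Cep120 KO 3, and 125 and 11.7 in Cep120 control 2. Y-linked RNA was 0 to 0.0628 CPM in Cep120 control 3 and Pkd1 controls 1 and 2.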
